A study of Mus musculus with 6 samples.

How the data were processed

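Gene expression was measured in 6 RNA samples of mouse haematopoietic progenitors, each on 1 Affymetrix whole-genome expression array. Per the labels' protocols, total RNA was extracted with a column kit and amplified and biotin-labelled with a kit that primes from the 3' end of the transcripts. The authors deposited log2 expression values per probe set, and per the submitters' processing notes these were made by RMA, which corrects background, quantile-normalizes the arrays and summarises the probes of each probe set. The version of the RMA software is not given in the sources used here. Scanner files were not used here, so neither background correction nor normalization could be redone from the probes. Because quantile normalization gives every array nearly the same distribution, a change in the total amount of RNA per cell cannot be read from these values.

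The table held 45101 probe sets, of which 64 were Affymetrix controls and 45037 were not. GEO's platform annotation gave 1 gene for 34945 of these, several genes for 932 and no gene in the table used here for 9160. Gene symbols were checked by Entrez identifier against RefSeq names of the mouse assembly GRCm38.p6, in which 34741 probe sets found their gene, and 0 symbols changed. One symbol shared by several Entrez identifiers was left out. No genome build is named for the array values, and no coordinates are given. A gene was represented by 1 probe set, among those annotated to it alone, with the highest mean over the 6 arrays, which gave 18192 genes, 9009 of them with more than 1 probe set. No filter on dim probe sets was applied. The 27 probe sets for bacterial poly-A control transcripts served as a measure of background. Their highest value on any array, 3.61, is used as a ceiling: where an array of the dimmer group lay below it, that array was set to the ceiling and the fold of a named gene is given as a lower bound, and where both group means lay below it, no fold is given. Tests, counts and list medians use the values as deposited, and a list median with values under the ceiling set to it is added where it differs. Arrays carry no read depth, and the number of arrays, 3 per group, limits the precision.

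Groups and replicate numbers were taken from the sample titles. The deposited log2 values were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, without trend or robust options, all 6 arrays, no covariate), as EGFP-positive minus EGFP-negative, with two-sided tests and Benjamini-Hochberg adjustment over all genes. The threshold was an adjusted p under 0.05. The same fit was made over all 45037 probe sets. For the probe sets of the introduced gene, an exact permutation test was added, which cannot go below 0.1 with 3 against 3 arrays. The 25 gene lists were tested with limma's camera with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the lists. Camera with a correlation estimated for each list and fry, limma's rotation test, were alternatives. Fry's directional test asks whether a list's genes move on balance one way and its mixed test whether they change in either direction, and neither compares the list with other genes.

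The groups, the design, the gene lists, the rule for named genes and the alternatives were fixed before the data were examined, except where an added choice is named. The rule named Mecom, the 14 genes with the largest rise and the 14 with the largest fall among genes past the threshold, and from each list up to 2 members that rose and 2 that fell with the smallest p, 107 genes in all. Members named beyond that rule, to spell out a small count or an exception, were chosen after their values were seen. Members with no probe set annotated to that gene alone were not analysed here. Of the listed symbols 1 was matched through its older name, Ddx58. The alternatives were the replicate number as a block, a further quantile normalization, arrays shifted to the same median, only genes whose mean lay above that of the median gene (the brighter genes), eBayes with trend or with robust options, array weights, other choices of probe set per gene and leaving out each array in turn. A filter at the background ceiling was added after the data were seen, as were 5 further gene lists (epithelial genes, plasma cell genes, myeloid immunoreceptors, chemokines and globins). The chemokine and globin lists held only part of their families, so all measured chemokine ligands and all measured alpha and beta globins, chosen by gene symbol, were tested too, with adjustment over these 2 families.

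The scripts were tested on simulated data with the spread of these arrays: 20 datasets of 18192 genes, 200 of them changed. The fit recovered 14.6% of genes changed by 0.5 on the log2 scale, 55.9% of those changed by 1 and 87.7% of those changed by 2, and 4.45% of its calls were false. In the real arrays 33.2% of genes passed the threshold, a far larger share than was changed here. A larger share loosens the cut-off on the unadjusted p, so these recovery rates are not those of the real fit. Camera called the shifted list in 20 of 20 datasets and 1 of 480 unshifted lists. Genes in these datasets varied independently, and list members were drawn at random. The simulation therefore does not show how often camera would falsely call real lists, whose members may be correlated.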

Results

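The series asked how forced expression of EVI1, a zinc finger transcription factor encoded by Mecom and overexpressed in some myeloid leukaemias, alters gene expression in haematopoietic progenitors. Lineage-negative marrow progenitors, depleted of mature blood cells, came from mice that carry a doxycycline-responsive transactivator in the Rosa26 locus. They were transduced with a lentiviral vector that expresses EVI1 together with the fluorescent protein EGFP when doxycycline is present, and were grown in stem cell factor (50 ng/ml), interleukin-3 (20 ng/ml), Flt3 ligand (50 ng/ml) and interleukin-11 (50 ng/ml). Doxycycline (1 µg/ml) was added the day after transduction, and 20 hours later the cells were sorted by EGFP. There were 2 groups, EGFP-positive and EGFP-negative, with 3 arrays each. The labels of the EGFP-negative samples call them untransduced, whereas the description of the design has a sort for negative or low EGFP from the transduced culture, and the description field of the EGFP-positive samples also carries the word untransduced. The groups used here are those of the sample titles. Each array measured a whole sorted fraction. Rises and falls below therefore compare the fractions, and a different mix of cells cannot be told apart from a change within cells. Nothing in the labels says that replicates came from separate cultures or animals, so p-values measure only the spread between these samples, which may be technical.

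The log2 expression values had medians of 5.11 to 5.14 on the 6 arrays. Across probe sets, Pearson's r was 0.995 between all pairs of EGFP-negative arrays, 0.989 between EGFP-positive arrays and 0.968 to 0.969 between groups. Between 99 and 300 of 45037 probe sets had an identical value in any pair of arrays, so no array was a copy of another. The 3' end signal of Actb exceeded its 5' end signal by 0.80 ± 0.05 (SD, n = 3) in EGFP-negative and 1.00 ± 0.03 in EGFP-positive arrays on the log2 scale, and for Gapdh the difference was 0.82 ± 0.02 and 1.06 ± 0.04. For Tfrc it was 5.03 ± 0.23 and 5.43 ± 0.29, whereas for Pcx it was lower in EGFP-positive arrays (1.88 ± 0.09 and 1.54 ± 0.32). The lowest 5' signals of Tfrc (4.26) and Pcx (3.92) lay near the ceiling of 3.61, so these differences say little. For Actb and Gapdh the lowest were 11.33 and 12.51. The 3' excess, a sign of RNA quality or amplification, moved with the groups for Actb and Gapdh and so stands beside every gene group below. Spiked hybridisation controls (18 probe sets) differed between groups by a median of 0.06.

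Mecom transcripts passed the test at none of 3 probe sets, and no rise was measured in EGFP-positive cells beyond the spread between arrays. The brightest, 1438325_at, read 8.26 ± 0.09 (SD, n = 3) in EGFP-negative and 7.97 ± 0.20 in EGFP-positive arrays, a difference of -0.29 (SE 0.13; limma, Benjamini-Hochberg adjusted p = 0.17 over probe sets and 0.13 over genes). Without EGFP-positive replicate 1 the gene-level difference became -0.41 with an adjusted p of 0.033. The remaining probe sets, 1422295_at and 1423011_at, read 2.84 ± 0.40 and 2.16 ± 0.10 in EGFP-negative and 2.97 ± 0.26 and 2.25 ± 0.14 in EGFP-positive arrays, within the range of bacterial control probe sets (1.13 to 3.61). Exact two-sided permutation tests gave p = 0.2, 0.7 and 0.7, where 0.1 is the smallest p that 3 against 3 arrays allow. Whether the EVI1 sequence of the vector holds the part matched by these probe sets, and from which species it comes, is not given in the sources used here, so these probe sets do not check the labels, and EGFP itself was not analysed here.

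The EGFP-positive fraction gained transcripts that were near background in the EGFP-negative fraction. Embryonic beta-like globin Hbb-y went from 2.01 ± 0.38 to 9.45 ± 0.14 on the log2 scale (n = 3), at least 57.3-fold higher, and Slc6a20a, an amino acid transporter, from 3.16 ± 0.60 to 10.31 ± 0.06, at least 104-fold higher. Esrp1, a splicing regulator of epithelial cells, rose at least 64.8-fold, and Slc4a1, the anion exchanger of the red cell membrane, at least 52.2-fold. Mmp9, a secreted gelatinase, rose 68.2-fold (4.62 ± 0.61 to 10.71 ± 0.12) and Tek, the angiopoietin receptor carried by endothelial and blood stem cells, at least 43.9-fold (3.76 ± 0.63 to 9.40 ± 0.29, with 1 EGFP-negative array under the ceiling). Muc1, Crb3 and Cldn7, which encode a membrane mucin, a polarity protein and a tight junction claudin of epithelia, rose 38.8-fold, 35.5-fold and 27.0-fold, Pdzk1ip1 rose 28.2-fold, and the desmosomal cadherin Dsc2 rose at least 12.3-fold. The other named rises were Ctsj (at least 25.9-fold), the angiotensin receptor gene Agtr1a (at least 16.0-fold) and Gsdmc2 (at least 14.5-fold). Adjusted p for these 14 genes ran from 1.5e-05 for Esrp1 to 0.00010 for Agtr1a (limma, Benjamini-Hochberg), and 8 of the 14 had an EGFP-negative mean under the highest bacterial control. With the mean of all probe sets of a gene the log2 rises were smaller for Slc4a1 (3.98), Crb3 (3.42) and Dsc2 (2.73), and their calls held.

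The largest falls took in genes of several blood lineages. Gas7 went from 9.46 ± 0.05 to 3.74 ± 1.26, with 2 of the 3 EGFP-positive arrays under the ceiling, and was at least 40.3-fold lower. Dntt, the terminal transferase of early lymphoid cells, was at least 35.9-fold lower. Ear3, an eosinophil-associated ribonuclease, was at least 27.1-fold lower, and Trem1, a receptor of myeloid cells, at least 22.3-fold lower. Falls were also seen for the myeloid receptor genes Cd300ld (at least 17.0-fold lower) and Siglece (-4.21), and for the immunoglobulin and T cell receptor segments Igha (-4.40), Igkv15-103 (at least 10.5-fold lower) and Trgv4 (-5.07). Tph1, an enzyme of serotonin synthesis, fell by 4.74, and Acaa1b, a peroxisomal thiolase, fell by 4.45. P2rx3, Slc24a3 and Crtac1 were at least 14.7-fold, 16.5-fold and 10.2-fold lower. Among these 14 genes the highest adjusted p was that of Crtac1, 0.0021 (limma, Benjamini-Hochberg). The probe sets that stand for Hbb-y, Slc4a1, Dntt, Ear3 and Igha are of a type that can also bind related sequences, so their signal may include close family members, but none of the 28 genes with the largest changes had a probe set past the threshold in the opposite direction. With the mean of all probe sets of a gene, the log2 differences of Gas7 (-2.26), P2rx3 (-3.02) and Crtac1 (-2.53) were smaller, and their calls held.

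**Figure D1:**
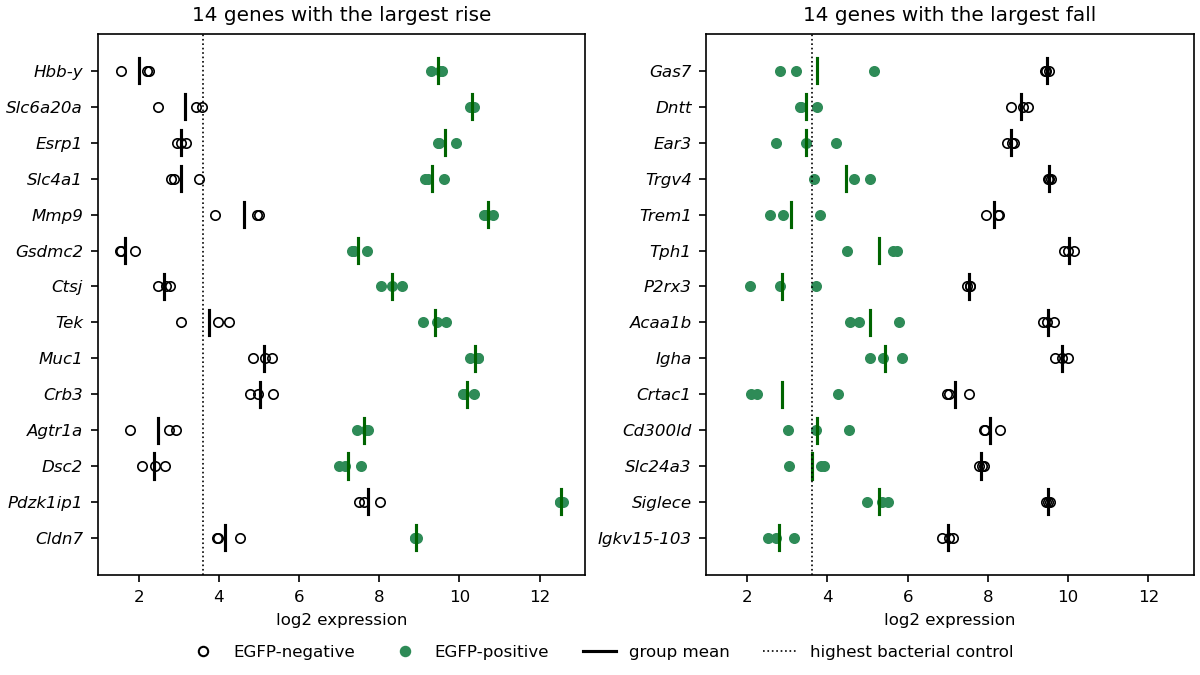
Log2 expression on each of the 6 arrays (horizontal axis) of the 14 genes with the largest rise (left) and the 14 with the largest fall (right); open circles are EGFP-negative and filled circles EGFP-positive arrays, bars are group means and the dotted line is the highest bacterial control, 3.61. The 3 Gas7 values of EGFP-positive arrays spread most (SD 1.26), and 8 of the rises and 7 of the falls have one group mean left of the dotted line.

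Over the whole table, 6045 of 18192 genes (33.2%) passed the threshold, 2913 higher and 3132 lower in EGFP-positive cells, and 1083 and 1135 of these changed at least 2-fold (limma, Benjamini-Hochberg). In 101 genes the mean rose from under the highest bacterial control to at least 2-fold above it. Over probe sets, 10874 of 45037 passed (24.1%), 5203 higher and 5671 lower. Of 3422 called genes with more than 1 probe set, 16 had a probe set past the threshold in the opposite direction. With only the brighter genes tested, the calls of at least 2-fold numbered 629 higher and 706 lower.

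**Figure D2:**
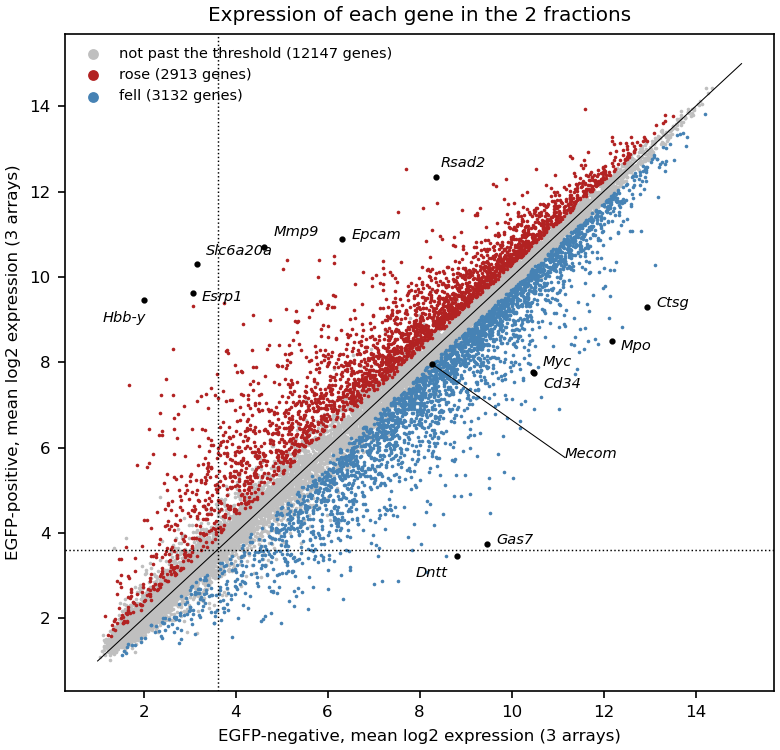
Mean log2 expression of each of 18192 genes in the EGFP-negative (horizontal axis) and EGFP-positive (vertical axis) fraction, 3 arrays each; red genes rose, blue genes fell and grey genes did not pass an adjusted p of 0.05, dotted lines mark the highest bacterial control (3.61) and the diagonal marks equal expression. Hbb-y, Slc6a20a and Esrp1 lie left of the vertical dotted line and far above the diagonal, Gas7, Mpo and Ctsg far below it, and Mecom close to it.

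Of 25 gene lists, camera called 15, of which 9 also passed with an estimated correlation: mitosis, DNA replication, G1 cyclins, cell cycle inhibitors, neutrophil, mast cell, interferon response, ribosome biogenesis and the unfolded protein response. The other 6 did not, and each is given with that p. Among these, the estimated correlation exceeded the preset 0.01 for erythroid genes (0.049). It lay below 0.01 for eosinophil (-0.031), p53 (-0.026), lymphoid (-0.018), monocyte (-0.001) and dendritic (0.001) genes. For the lists below the preset, a higher correlation between members therefore does not account for the lost call. Fry's mixed test, which asks only whether members change in either direction, passed for 25 of 25 lists.

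Cell cycle genes fell together in EGFP-positive cells. Of 31 mitosis and G2/M genes, 30 fell and 0 rose, among them Ccna2, a cyclin of S and G2 phase (-1.75, from 10.59 ± 0.04 to 8.84 ± 0.07, n = 3), and the spindle factor Tpx2 (-1.74), and Ttk did not pass (-0.82). Of 30 DNA replication genes, 27 fell, such as Dtl, which guides licensing factors to degradation (-2.19), and Rrm1, a ribonucleotide reductase subunit (-2.18), and 1 rose, the transcription factor gene E2f2 (1.47), while Rfc4 (-0.68) and Chaf1b (0.23) did not pass. The list medians were -1.74 and -1.73, with camera adjusted p of 9.2e-17 and 2.4e-14. Of 15 G1 cyclin and CDK genes, 10 fell, including Cdk6 (-1.94), Ccne2 (-1.55) and the growth regulator Myc (-2.70), and 2 rose, E2f2 and Cdk2 (0.34), with a list median of -0.84 (camera adjusted p = 0.00055). Of 18 cell cycle inhibitor genes, 12 rose and 2 fell (median 0.54, camera adjusted p = 0.00033). The rises included Gadd45g (1.71), Btg2 (1.05) and the CDK inhibitors Cdkn2a (1.96) and Cdkn1c (at least 3.56-fold), and the falls were Gadd45a (-1.16) and Ccng2 (-0.30). The counts adjusted over the list alone were 30 falls for mitosis, 28 falls and 1 rise for replication, 10 and 2 for G1 cyclins, and 13 rises and 2 falls for inhibitors. The calls of Cdk2 and Ccng2 were each lost without any 1 of the 6 arrays, with adjusted p up to 0.10 for Cdk2 without EGFP-negative replicate 1 and 0.11 for Ccng2 without EGFP-negative replicate 3. With the mean of all probe sets the changes were smaller but held for Dtl (-1.45) and Tpx2 (-0.84) and did not for Cdk2 (adjusted p = 0.11). Cdk2 was also lost with the replicate number as a block (0.068) and the most variable probe set (0.064), and Ccng2 with the block (0.10), other scalings (0.052 and 0.060), array weights (0.062) and the most variable probe set (0.084).

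Targets of p53 and apoptosis regulators moved both ways. Of 21 p53 target genes, 9 rose, such as Btg2 and the repair factor Ddb2 (0.88), and 2 fell, the BH3-only gene Pmaip1 (-1.42) and the kinase gene Plk2 (-1.34), with 10 and 3 adjusted over the list alone. The cell cycle inhibitor list also holds Btg2, Cdkn1a, Ccng1 and Trp53inp1. The p53 list median was 0.24 (camera adjusted p = 0.042), and adjusted p = 0.13 with an estimated correlation. Its call was also lost without 5 of the 6 arrays, all but EGFP-negative replicate 3, with adjusted p from 0.052 without EGFP-positive replicate 1 to 0.071 without EGFP-negative replicate 1. Plk2 was -0.66 with the mean of its probe sets and still passed. Of 18 apoptosis regulators, 6 rose and 5 fell, also over the list alone. The pro-apoptotic genes Bik and Bmf rose by 2.81 and 0.71, while the anti-apoptotic Bcl2 fell by 2.42 and the pro-apoptotic Pmaip1 also fell. Bmf did not pass with its most variable probe set (0.33, adjusted p = 0.50). As a list they did not pass (median 0.13, camera adjusted p = 0.77), and fry's directional test put them downward where median, mean and camera were upward.

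Granulocyte, mast cell and eosinophil genes were lower in EGFP-positive cells. Of 19 neutrophil granule and granulocyte genes, 17 fell, among them the granule enzymes Mpo (-3.69, from 12.18 ± 0.01 to 8.49 ± 0.22, n = 3) and Ctsg (-3.65), and 2 rose, Mmp9 and the G-CSF receptor gene Csf3r (0.66). The list median was -1.82, or -1.68 with values under the ceiling set to it (camera adjusted p = 1.7e-08). Of 14 mast cell and basophil genes, 12 fell and 0 rose, including carboxypeptidase Cpa3 (-3.46) and Hdc, which makes histamine (-3.65; median -1.80, camera adjusted p = 2.1e-09). Of 7 eosinophil genes, 4 fell: Prg2 (-2.85), Siglecf (at least 3.94-fold lower), Prg3 and Epx (median -2.35, or -1.98 with values under the ceiling set to it, camera adjusted p = 0.0036). The eosinophil list had an adjusted p = 0.071 with an estimated correlation. Of 18 monocyte and macrophage genes, 11 fell, such as F13a1 (-2.68) and Adgre1 (-2.07), and 6 rose, such as Mpeg1 (1.19) and Cd68 (0.80), for a median of -0.59 (camera adjusted p = 0.019), and adjusted p = 0.10 with an estimated correlation. Adjusted over the list alone, 17 neutrophil, 13 mast cell, 5 eosinophil and 11 monocyte genes fell, and 2, 0, 0 and 6 rose. The monocyte call was lost with eBayes trend (adjusted p = 0.058) and that of Csf3r without any 1 of 5 arrays, all but EGFP-positive replicate 1 (up to 0.067 without EGFP-negative replicate 3).

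Erythroid genes were mostly higher and platelet genes divided. Of 17 erythroid genes, 11 rose: besides Slc4a1 (at least 52.2-fold), the water channel gene Aqp1 (2.21, from 9.24 ± 0.02 to 11.45 ± 0.07, n = 3), the erythropoietin receptor gene Epor and the transcription factor genes Gata1 and Klf1. Alas2, the first enzyme of haem synthesis in red cells, fell by 1.86, and Hba-a1, under the ceiling in both groups, and Tfrc (0.09) did not pass. Alpha globin signal was not absent, since Hba-a2, not on this list, read 10.96 in EGFP-negative and 11.34 in EGFP-positive arrays. The list median was 0.48 (camera adjusted p = 8.5e-05), and adjusted p = 0.068 with an estimated correlation. Of 18 megakaryocyte and platelet genes, 8 rose, including the chemokine gene Ppbp (3.00) and the integrin gene Itga2b (0.97), and 4 fell, F2rl2 (-3.10), Plek (-1.39), Treml1 and Gfi1b. That list did not pass (median 0.37, camera adjusted p = 0.14), but with only the brighter genes its adjusted p was 0.034. When adjusted over the list alone, the counts were 11 rises and 1 fall for erythroid and 8 and 4 for megakaryocyte genes.

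Genes associated with haematopoietic stem cells went both ways. Of 27, 10 rose and 5 fell. Tek rose most, followed by Ctnnal1 (3.35, from 8.38 ± 0.01 to 11.72 ± 0.13, n = 3) and Slamf1 (2.59), the gene of CD150. The falls were Cd34 (-2.75), Mycn (-1.54), Procr, Kit and Prdm16 (-0.90). With the mean of its probe sets, of which 1 of 4 passed, Prdm16 was -0.21 (adjusted p = 0.33), while Mycn was -0.86 and still passed. The list did not pass (median 0.14, camera adjusted p = 0.43). Of 12 genes linked to EVI1 in earlier work, 3 rose, Adgrg1 (1.08), Zbtb16 (0.96) and Spi1, and 2 fell, Runx1 (-0.63) and, by its brightest probe set alone, Prdm16, while Gata2 (-0.15) and Meis1 (-0.24) did not pass. The median of this list was -0.08, its mean 0.02 and its camera direction downward (adjusted p = 0.98). Of 16 Hox genes, 3 rose, Hoxb3 (1.26), Hoxb4 and Hoxa10 (0.57), and 1 passed as lower, Hoxa11, whose means of 2.28 and 1.82 lay under the ceiling in both groups, so no fold is given. The Hox list did not pass (median 0.15, or 0.11 with values under the ceiling set to it, camera adjusted p = 0.16). The rises and falls adjusted over the list alone were 10 and 5, 3 and 2, and 3 and 0. The call of Hoxa11 was lost without any 1 of 5 arrays, all but EGFP-positive replicate 1, with adjusted p up to 0.14 without EGFP-negative replicate 3, and also with eBayes trend (0.052) or robust (0.053) options, arrays shifted to the same median (0.058), the most variable probe set (0.067) and the replicate block (0.080). Hoxa10 did not pass with the mean of its probe sets (0.31, adjusted p = 0.064).

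Lymphoid and antigen presentation genes fell in part, and stromal markers did not move as a list. Of 23 lymphoid genes, 8 fell, including Dntt and the cytotoxic granule gene Nkg7 (-3.59), 2 rose, the B cell receptor gene Cd79b (0.81) and the chemokine receptor gene Ccr9 (1.07, or 0.39 with an adjusted p of 0.058 as the mean of its probe sets, of which 1 of 5 passed), and 13 did not pass (median -0.21, or 0 with values under the ceiling set to it, camera adjusted p = 0.042). With an estimated correlation the lymphoid adjusted p = 0.13. Of 15 dendritic cell and MHC class II genes, 8 fell, such as H2-Eb1 (11.26 ± 0.04 to 10.22 ± 0.06, n = 3) and H2-Aa (-0.92), and 1 rose, Bst2 (1.06), which also belongs to the interferon list (median -0.52, camera adjusted p = 0.042). Here too the adjusted p = 0.13 with an estimated correlation. Of 12 stromal and endothelial genes, 4 passed as higher, Col1a1 (2.00, or 1.11 as the mean of its probe sets), Kdr (at least 1.68-fold), Cdh5 (at least 1.30-fold) and Postn, with both group means under the ceiling, and 1 fell, Pdgfrb (-1.31), with a median of 0.12, or 0.03 with values under the ceiling set to it (camera adjusted p = 0.55). Adjusted over the list alone the rises and falls were 2 and 9 for lymphoid, 1 and 8 for dendritic and 4 and 1 for stromal genes. The lymphoid call was lost without EGFP-negative replicate 1 (adjusted p = 0.057) or EGFP-positive replicate 1 (0.051), and the dendritic call without EGFP-negative replicate 2 (0.067) or EGFP-positive replicate 1 (0.052).

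Interferon response genes rose almost as a block. Of 25, 23 rose and 0 fell, also over the list alone, led by the antiviral genes Rsad2 (3.97, from 8.37 ± 0.10 to 12.33 ± 0.05, n = 3) and Oasl2 (2.89), while Cxcl10 (0.30) and Mx2, under the ceiling in both groups, did not pass. The list median was 1.41 (camera adjusted p = 2.6e-13).

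Signalling lists without a shared direction were those of TGF-beta and immediate early genes. Of 18 TGF-beta and SMAD feedback genes, 7 rose, including the inhibitory Smad6 (at least 2.25-fold) and Skil (0.86), and 6 fell, including Id2 (-2.25) and Ldlrad4 (-1.99), with a median of -0.05 (camera adjusted p = 0.77). As the mean of their probe sets, Skil (0.38, adjusted p = 0.089) and Ldlrad4 (-0.40, adjusted p = 0.072) did not pass, and 1 of 2 and 1 of 4 probe sets did. Of 18 immediate early genes, 5 rose, among them the nuclear receptor genes Nr4a2 (2.02, from 7.48 ± 0.08 to 9.50 ± 0.08, n = 3, or 1.30 as the mean of its probe sets) and Nr4a1, the mRNA decay factor Zfp36 (0.99), Fosl2 and Junb, and 7 fell, including Egr2 (-2.21) and Myc. The median of the immediate early list was 0.08, its mean -0.13 and its camera direction downward (adjusted p = 0.77). Adjusted over the list alone the rises and falls were 7 and 6, and 5 and 7.

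Growth and protein folding genes were lower. Of 20 ribosome biogenesis and MYC target genes, 18 fell and 0 rose, including the nucleolar Nop56 (10.36 ± 0.05 to 8.29 ± 0.10, n = 3) and Cad (-1.81), which starts pyrimidine synthesis (median -0.85, camera adjusted p = 1.1e-09). Of 16 unfolded protein and amino acid stress response genes, 11 fell, such as Atf4 (-0.84) and asparagine synthetase Asns (-1.17), and 1 rose, Trib3 (0.43), with a median of -0.73 (camera adjusted p = 0.00041). Of 18 glycolysis and hypoxia genes, 4 rose, Vegfa (1.37), Ddit4 (0.69), Pfkfb3 and Egln3, and 6 fell, including Adm (-1.35) and Car9 (-1.25), with a median of -0.13 (camera adjusted p = 0.22). Of 15 cholesterol synthesis genes, 11 did not pass. Fdft1 (0.50) and Srebf2 (0.28) rose and Lss (-0.75) and Sqle (-0.30) fell, and the list had a median of 0.02, a mean of -0.02 and an upward camera direction (adjusted p = 0.98). In the same order, the rises and falls adjusted over the list alone were 0 and 19, 2 and 11, 5 and 6, and 2 and 1. The calls of Trib3, Srebf2, Lss and Sqle were lost without 3, 5, 4 and 5 of the 6 arrays, with adjusted p up to 0.095 for Trib3, 0.11 for Srebf2 and 0.099 for Lss without EGFP-negative replicate 2, and 0.13 for Sqle without EGFP-negative replicate 1. As the mean of probe sets Fdft1 did not pass (0.28, adjusted p = 0.090) and Atf4 (-0.56) did, and Sqle was lost with other scalings (0.053 and 0.056) and the most variable probe set (0.097). With the replicate block the calls of Trib3 (0.073), Srebf2 (0.093), Lss (0.065) and Sqle (0.10) were lost.

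**Figure D3:**
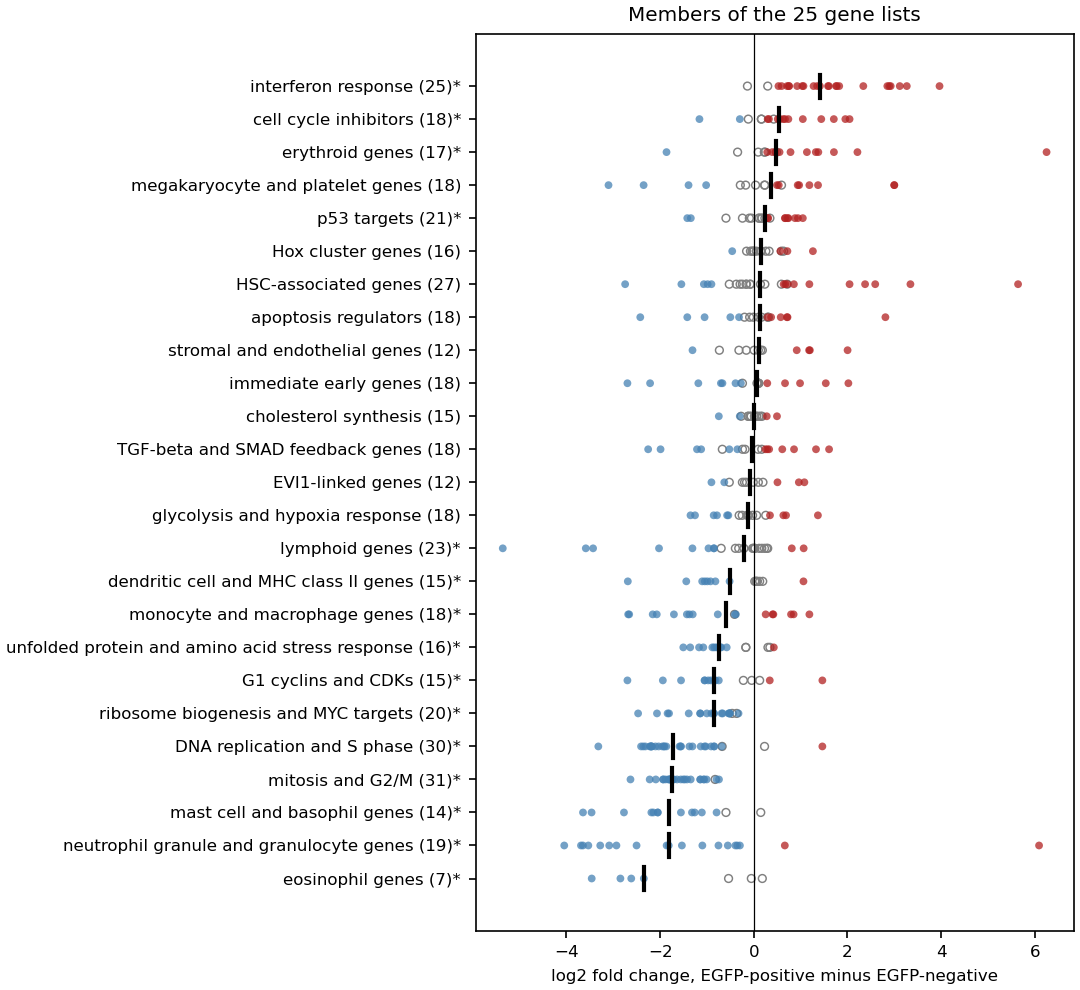
Log2 fold change (EGFP-positive minus EGFP-negative, horizontal axis) of each measured member of the 25 gene lists, with the number of members in brackets; filled points passed an adjusted p of 0.05 (red higher, blue lower), open points did not, black bars are list medians, all changes are as measured with no bound applied, and asterisks mark lists called by camera. The mitosis and replication lists lie almost wholly below 0 (medians -1.74 and -1.73) and the interferon list above it (median 1.41).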

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

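The filter at the background ceiling was chosen after the results were seen, and all other alternatives were planned. Genes past the threshold numbered 4432 to 6839 over the alternatives, against 6045, and probe sets 7398 to 12788, against 10874; leaving out 1 array gave 4432 to 5664 genes. With only the brighter genes, the calls of at least 2-fold were 629 higher and 706 lower, where fewer genes were tested. No scaling moved the median of all genes by more than 0.05. The replicate numbers are shared by the groups, but deviations of same-numbered arrays correlated at 0.012, -0.011 and 0.002 and 2 of 3 EGFP-positive arrays correlated best with their own number, so they were not taken as pairs. With the replicate number as a block, 4717 of the 6045 genes remained called in the same direction, 7 named genes lost their call (Ccng2, Cdk2, Hoxa11, Lss, Sqle, Srebf2 and Trib3), and among the lists p53 targets had an adjusted p of 0.056. In the following values p is the adjusted p of the list. With an estimated correlation, p was 0.068 for erythroid, 0.071 for eosinophil, 0.10 for monocyte, 0.13 for lymphoid and p53 and 0.13 for dendritic genes. With only the brighter genes, p was 0.057 for eosinophil, 0.17 for monocyte, 0.20 for dendritic, 0.11 for lymphoid and 0.034 for megakaryocyte genes, and stromal genes reversed (0.24). With eBayes trend, p was 0.058 for monocyte and 0.061 for dendritic genes. Fry's directional test, which compares a list with no other genes, gave adjusted p of 0.0021 for glycolysis, 0.0015 for Hox, 0.00044 for HSC-associated, 1.6e-05 for megakaryocyte and 0.012 for TGF-beta genes, and reversed apoptosis (0.00092) and EVI1-linked genes (0.19). Lists that were not called also reversed: cholesterol synthesis with array weights (0.97), the mean of probe sets (0.78) and the replicate block (0.98), EVI1-linked genes with the mean of probe sets (0.66) and renewed quantile normalization (0.90), and stromal genes with the mean of probe sets (0.99). Without 1 array, p ranged from 0.90 to 1.00 for cholesterol synthesis and 0.84 to 1.00 for EVI1-linked genes, both changing sign, 0.024 to 0.067 for dendritic, 0.034 to 0.057 for lymphoid and 0.034 to 0.071 for p53 genes, and the difference of the Mecom probe set 1422295_at from -0.10 to 0.27. Except where an alternative names its own construction, the cause was not tested. Camera was not run with robust eBayes, which it has no equivalent of, nor with the most variable probe set. Of 1686 comparisons for 107 named genes, 1618 kept direction and side of the threshold, 66 lost the call, 1 gained it (Mecom without EGFP-positive replicate 1) and 1 reversed (Mecom with the most variable probe set, a difference of 0.13). Signal near the bacterial controls limits what low values show.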

Other observations

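The 5 gene lists, the 2 whole gene families and the tests of explanations in this part were chosen after the results were seen; the interferon and cell cycle lists and their tests were planned. Epithelial genes rose in EGFP-positive cells: of 37 measured members of a list of junction, polarity and keratin genes, 26 rose and 1 fell, the claudin gene Cldn1 (31 and 2 adjusted over the list alone). The other 10 did not pass. Of these, Grhl2 (at least 1.30-fold), Rab25 (at least 1.28-fold) and Ap1m2 (-0.18) were lower. Esrp2 (11.40 and 11.61), Cldn3 (0.50), Cdh3 (0.33), Ovol1 (0.31) and Prss8 (at least 1.26-fold) were higher. Elf3 and Krt19 had both group means under the background ceiling. The cell adhesion gene Epcam rose 23.7-fold (6.31 ± 0.11 to 10.88 ± 0.05, SD, n = 3), the keratin gene Krt18 by 3.17 on the log2 scale, the desmosome gene Dsp 11.1-fold and the junction gene Ocln 7.82-fold, while Cdh1, bright in both groups (11.67 and 12.16), rose by 0.49. The list median was 1.28, or 1.02 with values under the background ceiling set to it (camera adjusted p = 6.2e-12 over the 5 added lists, 0.0058 with an estimated correlation). Without the 5 members that are among the largest rises, 21 of 32 rose (median 1.06, camera adjusted p = 1.6e-08). The remaining members were also listed after the results were seen, so that p is no independent check. Of the 37 genes, 26 already lay above the highest bacterial control in EGFP-negative cells. Among globins, Hbb-b2 rose with Hbb-y, by 1.86, whereas Hbb-bh1, Hba-a1 and Hba-x did not pass and had means under the background ceiling in EGFP-negative cells. The list of these 5 globins had a camera adjusted p of 0.011, which was lost with an estimated correlation (0.060) and without Hbb-y (0.097). It left out Hba-a2, which was bright in both groups (10.96 and 11.34) and rose by 0.38. All 6 measured alpha and beta globins had a camera adjusted p of 0.0088 over the 2 families, or 0.043 with an estimated correlation.

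Genes of mature immune function fell in a pair of further lists. Of 13 plasma cell genes, 9 fell and 0 rose, with a median of -1.64 (camera adjusted p = 1.7e-05). The falls included Igha, the joining chain gene Jchain (-3.86), the coactivator gene Pou2af1 (at least 5.30-fold lower) and Sdc1 (-2.28). Prdm1 (-0.07), Derl3 (-0.03), Eaf2 (0.04) and Tnfrsf17, under the background ceiling in both groups, did not pass. Of 24 myeloid immunoreceptor genes, 19 fell, among them Cd33 (at least 16.2-fold lower), Trem3 (-4.08), Cd300c2 (-3.66) and the Fc receptor gene Fcgr3 (-3.16), and 3 rose, the fungal lectin receptor genes Clec7a (1.23) and Clec4n (1.28) and Treml2 (0.55), with a median of -1.50 (camera adjusted p = 1.2e-07). With an estimated correlation the adjusted p were 0.013 and 0.0094. Without the members among the largest falls, 8 of 12 plasma cell and 16 of 21 immunoreceptor genes fell (camera adjusted p = 0.00010 and 5.9e-06). These members too were listed after the results were seen, so the values are no independent check. Chemokine genes went both ways. Of all 35 measured chemokine ligand genes, 13 fell, such as Ccl3 (-4.12) and Ccl4 (-3.46), 4 passed as higher, Ppbp (3.00), Ccl27a (1.46), Cx3cl1 (0.57) and Cxcl5, whose means lay under the background ceiling in both groups, and 18 did not pass, among them Pf4 (0.23). The family median was -0.12, or 0 with values under the ceiling set to it (camera downward, adjusted p = 0.0089 over the 2 families and 0.043 with an estimated correlation). A list of 19 of these genes, without Ppbp, Ccl27a and Cx3cl1, had a lower median (-0.81) and a smaller camera adjusted p (1.4e-06), so its result depends on which members it held.

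The cell cycle genes fell by a median of 1.74 over 61 measured list entries (quartiles -1.94 and -1.13). The spiked hybridisation controls differed by only 0.06 between groups, and upward, which argues against a scale shift left in the deposited values. Since these values were already quantile-normalized, the controls do not test scaling before that step, nor the amount of RNA per cell. Loss of RNA quality could contribute and stays open, since the 3' excess of Actb and Gapdh grew by a mean of 0.22 in EGFP-positive arrays. The changes of Tfrc (0.40) and Pcx (-0.34) went opposite ways and rest on 5' signals near background, so they decide little. How far each probe set lies from the 3' end is not known here. A response to the vector or to doxycycline-driven EGFP cannot be told apart from one to EVI1. The reason is that 0 of the groups carried a vector without EVI1. By the description of the design both fractions were sorted, so a response to sorting itself would be shared by them. The labels call the EGFP-negative samples untransduced, so this could not be checked. A different mix of cells in the 2 fractions cannot be told apart either, since each array measured a whole fraction. The median of -1.74 therefore belongs to all of these together.

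For the epithelial genes, a candidate source is a small number of epithelial cells in the EGFP-positive sort, although the culture began from lineage-negative blood progenitors. Such cells would bring abundant keratins, and the median of Krt7, Krt8, Krt18 and Krt19 lay -5.96 from Epcam in EGFP-positive arrays on the log2 scale, with 3 of them -5.24 to -7.39 from it but Krt18 only -0.51, and the Krt19 mean under the background ceiling. These levels come from different probe sets, which do not share a scale, so the test leaves this source open. For the median rise of 1.28, a response to the vector or to EGFP, or a different mix of cells, also cannot be told apart from a response to EVI1.

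The interferon response genes rose by a median of 1.41. Transduced cells may respond to lentiviral nucleic acid. EGFP-negative cells may carry less of the vector or none, which was not measured here. A reaction to the vector could therefore give the same rise as one to EVI1. With 0 groups that carried a vector without EVI1, the median of 1.41 cannot be told apart between them.

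The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. Genes past the threshold numbered 6045 in the real split and 0 in the highest other split. The 1 split of the 10 that reached the real value was the real split itself. For probe sets the values were 10874 and 0, with 1 split, and for lists called by camera 15 and 7, with 1 split. Each other split puts arrays of both groups on each side, so the group difference enters the spread within sides. This lowers the gene and probe set counts of those splits. Their 0 is therefore no measure of calls in data without a group difference. Nor are the 4 to 7 lists that camera called in those splits. The arrays of a group are divided unequally there, so part of the group difference stays between the sides.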
